A study of Homo sapiens with 12 samples.

How the data were processed

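The measurement was H3K4me3 ChIP-seq of the human endometrial stromal fibroblast line T HESC (ATCC CRL-4003) in ESF normoxia, ESF hypoxia and DSC hypoxia. Each condition had 2 H3K4me3 libraries and 2 input libraries, labelled A and B. Cells were cross-linked with formaldehyde and chromatin was sonicated to 200 to 600 bp, per the labels' protocols, and sequenced on an Illumina Genome Analyzer II with 75 bp reads. The submitters' processing notes name CASAVA 1.4, FastQC, Bowtie2 and MACS2 and the builds hg19 and GRCh37. The threshold of the peak caller, and whether reads of A and B were pooled before calling, are not given in the sources used here.

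The authors deposited 1 list of merged broad peaks per condition, whose values are the start and end positions of each peak in bp. The lists hold no peak height, fold enrichment, significance or read count, so depth per library is unknown and peaks could not be ranked by strength. Peak names joined in 1 entry and smallest gaps of 3002, 3002 and 3003 bp between neighbours show that called peaks up to about 3 kb apart had been combined before deposit. Joined entries made up 9.37% of the peaks in ESF normoxia, 7.85% in ESF hypoxia and 9.10% in DSC hypoxia, with at most 16 called peaks in 1 entry. A broad entry may therefore hold stretches without signal, and a small change at the gap between peaks can move breadth by a large step. Breadth also depends on depth and on the input, which the lists do not allow to be corrected.

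Positions were used as deposited on hg19 and are printed counting from 1. Peaks on chromosomes 1 to 22 and X were kept, which left 31233 peaks in ESF normoxia, 29882 in ESF hypoxia and 31706 in DSC hypoxia. Overlap meant at least 1 shared bp. Overlapping peaks of the 3 lists were combined into regions, and the breadth of a region in a list was the summed width of its peaks there. Breadth was compared as log2((breadth + 500 bp)/(breadth + 500 bp)), in regions of at least 1000 bp in 1 of the 2 lists compared, and a region counted as broader or narrower at 2-fold or more. The ratio understates the change of narrow regions. A gained or lost region had a peak in one list and none in the other. Broadest regions were the 500 of greatest breadth in each list, and their overlap was set beside that of independent lists. Shares carry Wilson 95% intervals.

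Before the data were examined, breadth was to be measured at transcription start sites and summarised over 21 gene lists. The gene table used here is on another assembly (GRCh38.p14), and hg19 gene positions were not used here, so regions took the place of genes and no gene list was computed. This change was made after seeing the data. By the rule fixed beforehand for that case, regions to be named were the 10 broadest peaks of each list and the 10 broadest without overlap in the list compared. The 8 largest increases and the 8 largest decreases with a peak in both lists, planned for genes, were carried over to regions, and regions broad in 1 list or in the hypoxia lists alone were ranked by the size of the difference, both chosen after seeing the data. The text describes examples from these sets and does not name every member. Cytogenetic bands came from the hg19 table of circlize 0.4.16 in R 4.3.3. A region was called near a centromeric or heterochromatic band within 5 Mb of one. Genes named for a band are members of the lists fixed beforehand and serve as background.

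Each condition had 1 list, so no test across replicates, no leaving out of libraries and no pairing by letter could be done. Comparisons were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9. The steps were tested on simulated data made from the real peaks. For ESF hypoxia against ESF normoxia (31233 peaks) and for DSC hypoxia against ESF hypoxia (29882 peaks), 200 of 200 peaks with changed width, 300 of 300 removed and 300 of 300 added peaks were found. The changed peaks were 50 each widened 4-fold or 3-fold and narrowed 5-fold or 4-fold, and all 50 of each kind were found in both. They were of moderate width with a long gap beyond the end that was moved, and added peaks lay in long gaps. Recovery was therefore easy by construction. Changes near 2-fold, in narrow peaks or among joined peaks were not simulated. The overlap of changes against the shared normoxia list was compared with 100 simulations. Alternatives covered the minimum peak width, joining distance, overlap, pseudocount, minimum breadth, scaling, threshold and size of the broadest set, and leaving out chromosome X or regions near centromeric bands.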

Results

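H3K4me3, a histone mark found mainly around active transcription start sites, was profiled by ChIP-seq in the human endometrial stromal fibroblast line T HESC (ATCC CRL-4003), an immortalised line. Undifferentiated endometrial stromal fibroblasts (ESF) were kept in normoxia or exposed to 1% O2 for 16 h. Decidual stromal cells (DSC) were the same cells decidualized in culture for 2 days with 0.5 mM 8-Br-cAMP and 0.5 µM medroxyprogesterone acetate before the hypoxia. Decidualization is the differentiation of stromal fibroblasts that prepares the uterine lining for implantation. The 12 libraries fell into 6 groups of 2, an H3K4me3 and an input pair for each of ESF normoxia, ESF hypoxia and DSC hypoxia; DSC in normoxia were not analysed here. Each condition was represented by 1 merged list of broad peaks, so no difference below has a replicate check, no p-value is given, and calls are by size only. Sequencing depth per library is unknown, and the 95% Wilson intervals on shares cover counting error only. The design asked how 16 h of hypoxia altered the breadth of H3K4me3 in ESF, and how DSC differed from ESF when both were hypoxic. Positions are given on hg19, regions are named by cytogenetic band, and no peak was assigned to a gene; genes mentioned as background lie in the same band.

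The 3 lists were of similar size, and the ESF hypoxia list covered the least sequence. On chromosomes 1 to 22 and X, ESF normoxia held 31233 peaks over 54.8 Mb, ESF hypoxia 29882 peaks over 48.9 Mb and DSC hypoxia 31706 peaks over 54.2 Mb. Median peak widths were 1088, 1127 and 1060 bp, respectively. Broad peaks were fewest in ESF hypoxia: 1795 peaks (5.75%) reached 5 kb in ESF normoxia, 1319 (4.41%) in ESF hypoxia and 1733 (5.47%) in DSC hypoxia. Peaks of 10 kb or more numbered 211, 137 and 225. The 95th percentile of width was 5279 bp in ESF normoxia, 4755 bp in ESF hypoxia and 5177 bp in DSC hypoxia. Between 25.4% and 27.4% of the peaks in a list were under 500 bp wide.

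**Figure D1:**
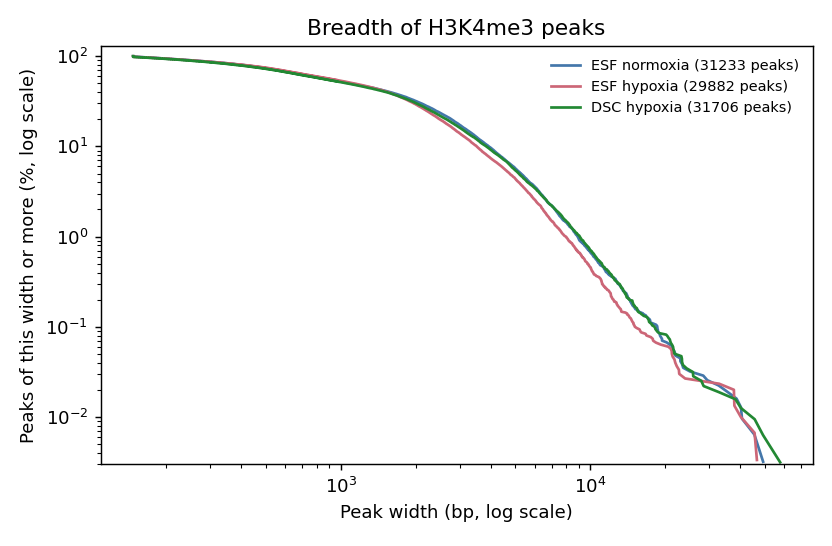
Share of peaks (percent, log scale) at or above each peak width (bp, log scale) for the 3 peak lists, with 1 line per list. The ESF hypoxia line runs below the others between about 2 and 20 kb, where 4.41% of its peaks reached 5 kb against 5.75% in ESF normoxia and 5.47% in DSC hypoxia.

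Overlapping peaks of the lists were combined into 41800 regions, and a core of these was marked in every condition. All 3 lists had a peak in 22333 regions (53.4%), with median breadths of 1740 bp in ESF normoxia, 1615 bp in ESF hypoxia and 1699 bp in DSC hypoxia. Regions marked in a single list were narrow: 5333 in ESF normoxia (median 354 bp), 3167 in ESF hypoxia (314 bp) and 5344 in DSC hypoxia (332 bp). Another 2223 regions were marked in both hypoxia lists and not in normoxia, 1816 in both ESF lists and not in DSC, and 1584 in ESF normoxia and DSC hypoxia but not in ESF hypoxia. Of the regions that reached 3 kb in some list, 6395 were marked in all 3 conditions.

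The broadest H3K4me3 domains of these cells were largely shared by the 3 conditions. At 15q26.2 (chromosome 15, 96860605 to 96910022), in the band that holds NR2F2, a nuclear receptor gene of the uterine stroma, peaks spanned 49.4 kb in ESF normoxia, 46.6 kb in ESF hypoxia and 49.3 kb in DSC hypoxia. Bands that hold HOX clusters carried domains of similar size in the 3 lists. One lay at 2q31.1 (chromosome 2, 176967378 to 177006021; 38.6, 37.9 and 38.2 kb), in the band of HOXD10 and HOXD11, and one at 7p15.2 (chromosome 7, 27200099 to 27232998; 32.7, 32.9 and 32.8 kb), in the band of HOXA10 and HOXA11. HOXA10 and HOXA11 encode homeobox factors needed for decidualization. Domains at Xq23 (chromosome X, 114959703 to 115005385) and 1q42.13 (chromosome 1, 228744088 to 228784333) also kept their size, at 45.5 to 45.7 kb and 40.2 kb. They were, however, chains of many called peaks. In ESF normoxia, ESF hypoxia and DSC hypoxia, 16, 16 and 15 were joined at Xq23 and 12, 7 and 14 at 1q42.13. Their extent may therefore include stretches without signal. Repeated sequence and read mapping there were not examined, so their like extent may not reflect the mark alone.

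Among the 500 broadest regions of each list, 278 (55.6%) were in all 3, where independent lists would share 0.0715. In that list alone were 22.6% of the 500 in ESF normoxia, 21.8% in ESF hypoxia and 22.4% in DSC hypoxia. Lists of 1 mark in the same line are not independent, so the values for independent lists are a weak yardstick. ESF normoxia and ESF hypoxia shared 334, ESF hypoxia and DSC hypoxia 335, and ESF normoxia and DSC hypoxia 331, each against 5.98 for independent lists. Within the 278, the broadest of the 3 values exceeded the narrowest by a median of 1.14 times, and in 46 regions by more than 1.5 times. The smallest of the 500 measured 7764 bp in ESF normoxia, 6917 bp in ESF hypoxia and 7925 bp in DSC hypoxia.

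Several of the very broad domains did differ in size. The domain at 7q33 (chromosome 7, 134462443 to 134522566) measured 34.0 kb in ESF normoxia, 53.7 kb in ESF hypoxia and 57.8 kb in DSC hypoxia. Its widest entry measured 28.4, 37.8 and 57.8 kb in that order and joined 6, 9 and 14 called peaks. Part of this difference may therefore be gaps that were bridged. At 7q21.3 (chromosome 7, 94021007 to 94049012), in the band that holds the type I collagen gene COL1A2, breadth was 12.6 kb in ESF normoxia, 17.4 kb in ESF hypoxia and 27.9 kb in DSC hypoxia. By contrast, 18q23 (chromosome 18, 74157611 to 74208848) had 47.9 kb in ESF normoxia, 36.0 kb in ESF hypoxia and 47.6 kb in DSC hypoxia. Breadth at 7q32.3 (chromosome 7, 130572400 to 130607748) was 35.3 kb in ESF normoxia and 21.9 and 25.4 kb in hypoxic ESF and DSC.

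**Figure D2:**
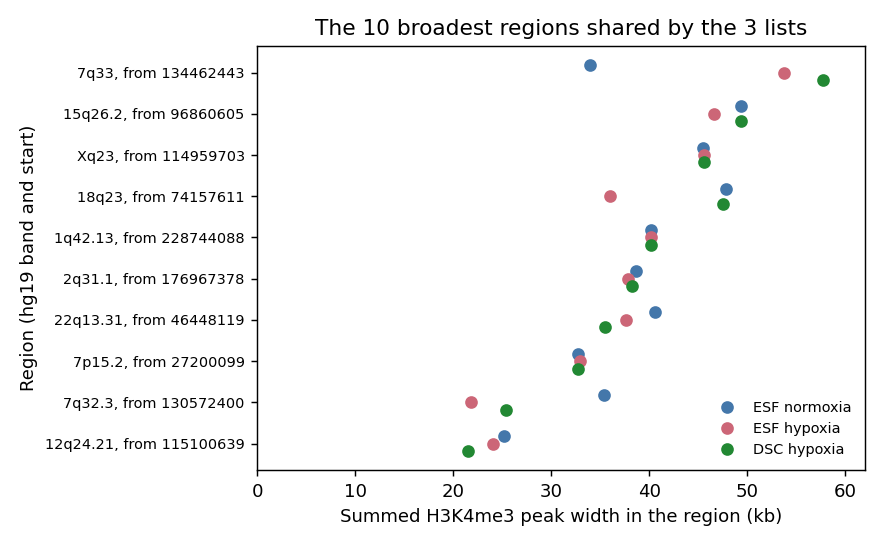
Summed H3K4me3 peak width (kb) in the 10 regions of greatest breadth among those broad in all 3 lists, with 1 point per list and regions named by hg19 band and start. The 3 points nearly coincide at Xq23, 1q42.13, 2q31.1 and 7p15.2, whereas 7q33 spans 34.0 to 57.8 kb.

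In ESF, 16 h of hypoxia went with narrower H3K4me3 at more regions than broader. Of 17872 regions with at least 1 kb in 1 of the 2 lists, 1450 (8.11%) were narrower in hypoxia by 2-fold or more and 824 (4.61%) were broader. By log2 ratio, which favours regions that are narrow in one list, the largest gains at regions marked in both lists were at 13q32.1 (chromosome 13, 95359570 to 95366018; 229 bp in normoxia, 6449 bp in hypoxia, log2 ratio 3.25) and 17q12 (chromosome 17, 35289307 to 35295266; 196 and 5960 bp, 3.21). The largest loss by this ratio was at 17q24.2 (chromosome 17, 66374100 to 66381317; 7218 bp in normoxia, 197 bp in hypoxia, −3.47).

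Further regions that were narrow in normoxia and broad in hypoxia were at 10q25.3 (chromosome 10, 118922349 to 118928133; 187 and 5773 bp), 10q24.31 (chromosome 10, 102495082 to 102505935; 744 and 10815 bp) and 3q24 (chromosome 3, 147071988 to 147079224; 317 and 6819 bp). The remaining regions of the 8 largest increases were at 2q35, 1q32.1 and 20p11.23, with log2 ratios of 3.16, 2.99 and 2.87, and the last lay within 5 Mb of a centromeric or heterochromatic band. Some of these kept their breadth in hypoxic DSC, with 5476 bp at 17q12 and 5711 bp at 10q25.3. Others had little there, with 1558 bp at 10q24.31 and 770 bp at 3q24. A second domain at 10q25.3 (chromosome 10, 118890797 to 118897211) had no peak in ESF normoxia, 6293 bp in ESF hypoxia and 6238 bp in DSC hypoxia. Another at 12q23.3 (chromosome 12, 106975177 to 106980931) had none in ESF normoxia, 5613 bp in ESF hypoxia and 2581 bp in DSC hypoxia. Of the 10 broadest gained regions, 6 lay within 5 Mb of centromeric or heterochromatic bands, among them the broadest, at 1q21.1 (chromosome 1, 142929347 to 142941880), with 11944 bp in ESF hypoxia.

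The 8 regions with the largest decreases in log2 ratio in hypoxic ESF were narrow in hypoxic DSC too, at 947 bp or less. They were picked for a high normoxia value against a low ESF hypoxia value. An outlying value in the normoxia list alone would therefore give the same picture. After 17q24.2, where DSC had 607 bp, the next were 19p13.12 (chromosome 19, 14616555 to 14622108; 5540 bp in normoxia, 200 bp in ESF hypoxia, 717 bp in DSC hypoxia) and 14q11.2 (chromosome 14, 23316913 to 23322964; 6052, 376 and 467 bp). The other members of the 8 largest decreases, at 19p13.3, 9q22.32, 10q25.1, 15q26.1 and 1q32.1, had log2 ratios from −2.90 to −2.69. Of the 8, only 14q11.2 lay near a centromeric or heterochromatic band. The ratio at 10q25.1 was −2.76 and that at 19p13.12 was −3.11, and both came under 2-fold when neighbouring peaks were joined over longer distances. Of the 10 broadest regions lost altogether, 3 lay near centromeric or heterochromatic bands, at 22q11.21, 1p11.2 and 7q11.21. The broadest was at 13q32.3 (chromosome 13, 99959615 to 99967717), with 8103 bp in ESF normoxia, no peak in ESF hypoxia and 147 bp in DSC hypoxia. At 3q25.1 (chromosome 3, 150165389 to 150170475), 5087 bp in normoxia faced none in ESF hypoxia and 312 bp in DSC hypoxia. Of the 10 broadest lost regions, 9 had 561 bp or less in DSC hypoxia, and the exception, 4p15.2 (chromosome 4, 27006153 to 27012089), had 4485 bp in ESF normoxia, none in ESF hypoxia and 5852 bp in DSC hypoxia. The lost regions too were picked on the normoxia list, and no value for regions so chosen without a change was computed.

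Most peaks were nevertheless present in both ESF lists. Hypoxia peaks overlapped 77.6% of the normoxia peaks (24235 of 31233, interval 77.1 to 78.1%), and normoxia peaks overlapped 81.7% of the hypoxia peaks (24403 of 29882, 81.2 to 82.1%). The lists shared 41.6 of 62.1 Mb, a Jaccard index of 0.671. Peaks without a partner were narrow, with medians of 379 bp in normoxia and 368 bp in hypoxia against 1599 and 1483 bp for those with one. In regions, 5390 were gained and 6917 lost, and 45 and 79 of these reached 3 kb. In the 24149 regions with a peak in both, the median log2 width ratio was −0.08 (interquartile range −0.35 to 0.12), and 62.1% (15000 regions, interval 61.5 to 62.7%) were narrower in hypoxia. Counting only regions with a peak in both lists gave 421 broader and 923 narrower regions.

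**Figure D3:**
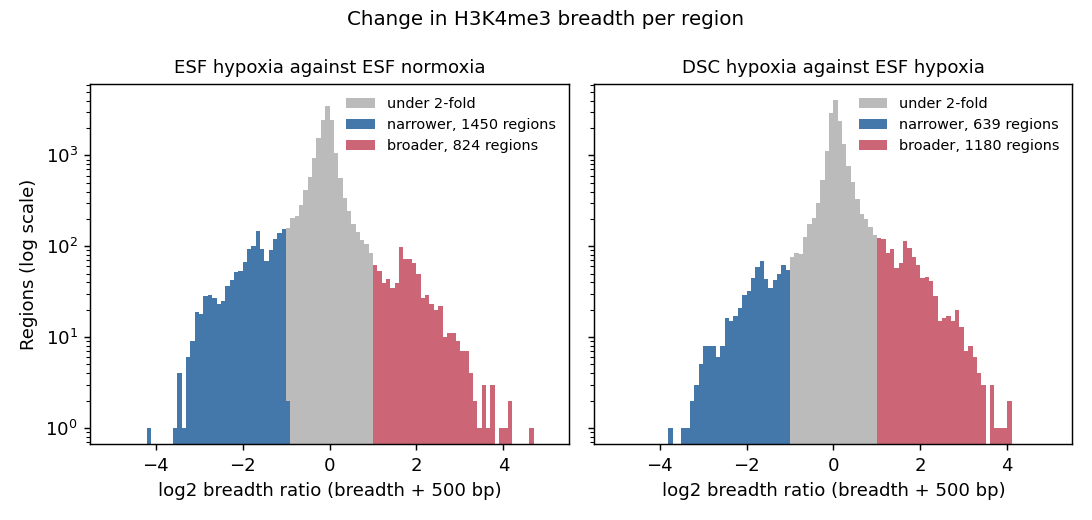
Histograms of the log2 breadth ratio per region (bins of 0.1, number of regions on a log scale) for ESF hypoxia against ESF normoxia on the left and DSC hypoxia against ESF hypoxia on the right, with regions at 2-fold or more in colour. The left panel holds 1450 narrower and 824 broader regions, and the right panel 639 narrower and 1180 broader.

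With both cell states hypoxic, DSC had broader H3K4me3 than ESF at more regions than narrower. Of 17546 regions, 1180 (6.73%) were broader in DSC by 2-fold or more and 639 (3.64%) were narrower. The list compared with here, ESF hypoxia, covered the least sequence of the 3; against ESF normoxia, which differs in both oxygen and cell state, DSC hypoxia had 1326 broader and 1397 narrower of 18295 regions. A cluster lay at 5q12.3, where 3 domains of DSC had almost no counterpart in ESF. They covered chromosome 5, 65274593 to 65282854 (318 bp in ESF normoxia, 175 bp in ESF hypoxia, 8262 bp in DSC hypoxia, log2 ratio 3.70 against ESF hypoxia), 65256385 to 65263989 (7605 bp in DSC, no peak in either ESF list) and 65245233 to 65252067 (6835 bp in DSC, no peak in either). At 2p14, the band that holds MEIS1, a homeobox transcription factor gene, a region from 66686924 to 66693663 on chromosome 2 had 258 bp in hypoxic ESF and 6740 bp in DSC (3.26). Another from 66719691 to 66724444 had 147 and 4754 bp (3.02).

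At 6q23.1 (chromosome 6, 130727778 to 130733794), breadth was 170 bp in hypoxic ESF and 5952 bp in DSC. The other 4 of the 8 largest increases, at 16p11.2 (2 regions), 20p11.1 and 1q21.1, lay within 5 Mb of centromeric or heterochromatic bands. The largest decrease by log2 ratio was at 4q21.21 (chromosome 4, 81156489 to 81162939), with 5728 bp in hypoxic ESF, 158 bp in DSC (−3.24) and 6016 bp in ESF normoxia. A region at 15q26.2 (chromosome 15, 96816179 to 96820234), some way from the very broad domain in the same band, had 3425 bp in ESF normoxia, 3919 bp in ESF hypoxia and 147 bp in DSC (−2.77). The remaining decreases, at 9q34.3, 10q24.33, 2q32.2, 3q13.2, 2p12 and 7q21.11, had ratios from −2.78 to −2.54. The one at 7q21.11 turned to 0.23, and that at 3q13.2 came under 2-fold, when neighbouring peaks were joined over longer distances. Among regions lost altogether in DSC, 5p15.31 (chromosome 5, 9712998 to 9717540) had 4079 bp in ESF normoxia and 4543 bp in ESF hypoxia, and 6q23.2 (chromosome 6, 132452213 to 132457049) had 492 and 4837 bp.

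Peaks of hypoxic ESF overlapped 77.8% of the DSC peaks (24664 of 31706, interval 77.3 to 78.2%), and DSC peaks overlapped 82.9% of those of hypoxic ESF (24772 of 29882, 82.5 to 83.3%). The Jaccard index was 0.695, with 42.3 of 60.8 Mb shared. DSC gained 6928 regions with a median of 348.5 bp and lost 4983 with a median of 340.0 bp, and 53 and 28 of these reached 3 kb. In the 24556 regions marked in both, the median log2 width ratio was 0.06 (interquartile range −0.12 to 0.29), and 39.5% (interval 38.9 to 40.2%) were narrower in DSC. With regions marked in both lists alone, 736 were broader and 416 narrower.

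**Figure D4:**
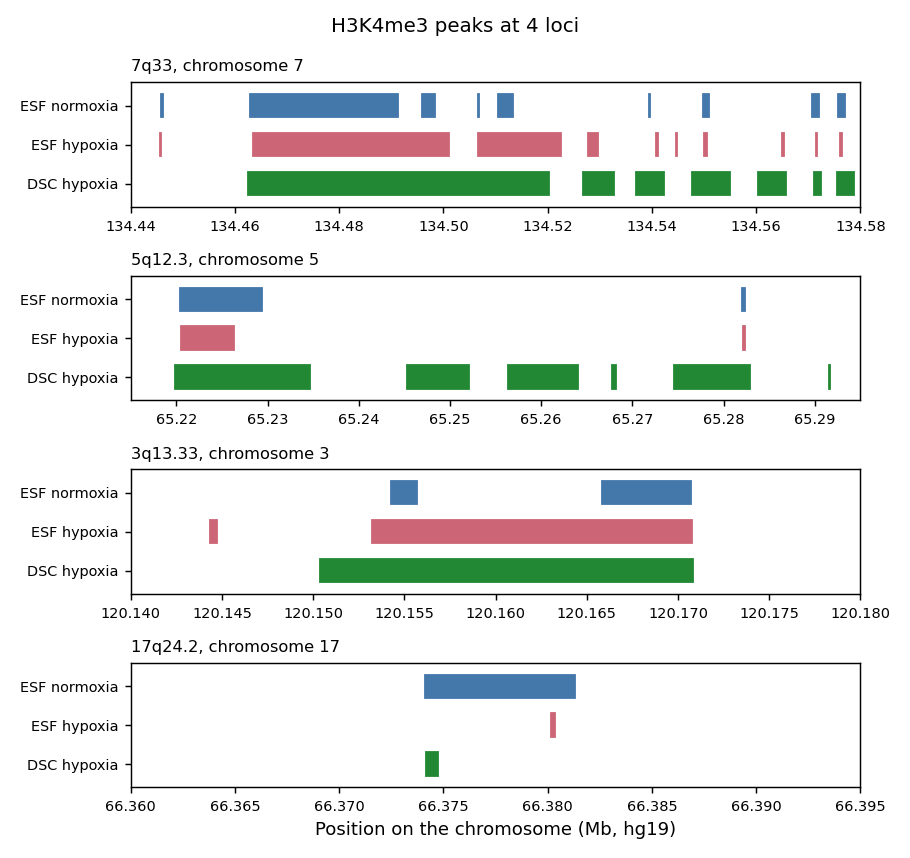
Positions of the H3K4me3 peaks (filled boxes, to scale, Mb on hg19) of the 3 lists at 4 loci. At 7q33 the peaks of DSC hypoxia form the widest block (57.8 kb), at 5q12.3 DSC hypoxia alone has peaks over 65245233 to 65263989, at 3q13.33 both hypoxia lists fill a stretch that is split in ESF normoxia, and at 17q24.2 the 7218 bp of ESF normoxia shrink to 197 and 607 bp.

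Set side by side, the 3 lists held regions that were broad in both hypoxia lists and others that were broad in a single list. ESF hypoxia shared 335 of its 500 broadest regions with DSC hypoxia and 334 with ESF normoxia, so among the broadest regions the hypoxia lists did not stand out as a pair. Over all peaks they were the closest pair, with a Jaccard index of 0.695. It was 0.671 for ESF hypoxia with ESF normoxia and 0.653 for DSC hypoxia with ESF normoxia. With 1 list per condition, how far this index varies between lists of the same condition is unknown. Of the 500 broadest regions of each list, 57 were among those of both hypoxia lists and not of ESF normoxia. Of the 8 with the largest gain over ESF normoxia, 3 lay near centromeric or heterochromatic bands, at 1q21.1 (2 regions) and 1q12. Away from these was 3q13.33 (chromosome 3, 120150394 to 120170815), with 6278 bp in ESF normoxia, 17512 bp in ESF hypoxia and 20422 bp in DSC hypoxia. Another was 17q21.33 (chromosome 17, 48341473 to 48351036), with 4071, 9486 and 9506 bp in the same order. It lay in the band that holds the collagen gene COL1A1, but the distance to that gene was not measured. By each list's own cut-off, 113 regions were broad in ESF normoxia alone, and with 1 width of 5319 bp in every list 372 were. That width lies below the cut-off of each list, and regions broad in all 3 lists rose with it too, from 278 to 849. Of the 113, 4q21.21 (chromosome 4, 81185694 to 81201209) had 15516 bp in normoxia and 6006 and 4727 bp in hypoxic ESF and DSC. At 1p32.3 (chromosome 1, 51432751 to 51447816) the values were 15066, 6458 and 6440 bp. Broad in DSC alone were 112 regions, led by 9q33.1 (chromosome 9, 118914066 to 118935826), with 20943 bp in DSC and 6230 and 5533 bp in normoxic and hypoxic ESF. The next 2, both at 16p11.2, lay near centromeric or heterochromatic bands. Hypoxic ESF alone had 109, among them 16q24.2 (chromosome 16, 87892503 to 87903589), with 11087 bp against 2879 bp in ESF normoxia and 3087 bp in DSC.

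Over 19055 regions with 1 kb or more in some list, 932 were broader in ESF hypoxia than in ESF normoxia by 2-fold or more, and 569 of these (61.1%) were also broader in DSC hypoxia. In 100 simulations with noise alone the share was 25.2%, and independent calls would give 69.2 regions. Likewise, 941 of the 1500 narrower regions (62.7%) were narrower in both hypoxia lists, against 25.2% in the simulations and 113.6 regions from independent calls. The covariance of the log2 ratios was 0.356 against a simulated 0.195. The simulations gave each list the same normally distributed noise (SD 0.441), set from DSC hypoxia against ESF hypoxia. The shape of the real noise was not checked, and noise with fewer but larger deviations could give a higher share. The independent calls leave out the shared normoxia list, so neither comparison allows for a noisier normoxia list. That list could not be split, and part or all of the excess may come from it. By the 2-fold threshold, 735 regions were broader in DSC hypoxia than in both ESF lists and 368 were narrower.

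**Figure D5:**
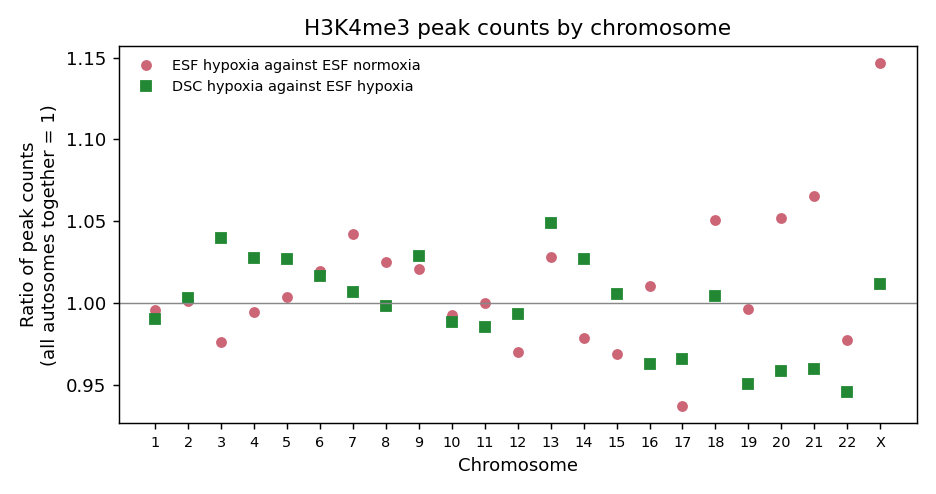
Ratio of H3K4me3 peak counts per chromosome, scaled so that all autosomes together equal 1, for ESF hypoxia against ESF normoxia (circles) and DSC hypoxia against ESF hypoxia (squares). For ESF hypoxia, chromosome X lies at 1.147 and the autosomes between 0.937 and 1.065.

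Chromosome X had the highest ratio of peak counts in hypoxic against normoxic ESF, although some chromosome must rank highest and no interval was computed for its ratio. It held 785 peaks in ESF normoxia, 858 in ESF hypoxia and 921 in DSC hypoxia. Scaled to the autosomes, the ratio of ESF hypoxia to ESF normoxia was 1.147 on X and 0.937 to 1.065 on the autosomes. For DSC hypoxia against ESF hypoxia it was 1.012, within the range of 0.946 to 1.049. Among peaks of 1000 bp or more, the X ratio of ESF hypoxia to ESF normoxia was 1.018, within the 0.945 to 1.044 of the autosomes. The sequence covered on X did not rise, with 1467 kb in ESF normoxia and 1380 kb in ESF hypoxia.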

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

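Leaving out regions near centromeric and heterochromatic bands, leaving out chromosome X, joining peaks under 5000 bp apart and forming regions over 2 lists were alternatives chosen after seeing the data; the others were planned. Of 140 alternative values of the main results, 103 stayed within 1.5 times the main count or within the counting interval of the share, and 37 moved. In ESF hypoxia against ESF normoxia narrower regions outnumbered broader ones, and in DSC hypoxia against ESF hypoxia broader ones outnumbered narrower ones, under each alternative run. Joining peaks under 1000 bp apart changed nothing, since no gap was that short, so its values among the 103 were fixed in advance. Leaving out chromosome X, with 2.51 to 2.90% of the peaks of a list, could hardly move a count either. The 103 therefore overstate how stable the results are. With peaks of 500 bp or wider, 82.4% of ESF normoxia and 85.5% of ESF hypoxia peaks overlapped each other, as did 87.4% of ESF hypoxia and 84.3% of DSC hypoxia peaks; 3200 regions were gained and 4014 lost in ESF hypoxia, 3578 gained and 2778 lost in DSC. In the same order, an overlap of 50% of the peak gave 68.7, 75.1, 76.9 and 70.5%, and 50% of both peaks 63.8, 66.7, 70.1 and 66.1%. Broader and narrower regions in ESF hypoxia, then in DSC, were 2241 and 3284, then 2889 and 1888, with no minimum breadth. They were 421 and 923, then 736 and 416, with a peak in both lists, and 1304 and 2364, then 1945 and 1037, at a threshold of 1.5-fold. These changes follow from more or fewer regions being counted. The broadest regions shared by all 3 lists, by both hypoxia lists alone and found in ESF normoxia alone were 573, 131 and 216 for the 1000 broadest, and 849, 102 and 372 for 1 width of 5319 bp in every list. Joining peaks under 5000 bp apart gave overlaps of 78.7% (ESF normoxia), 83.3% (ESF hypoxia by DSC hypoxia) and 78.4% (DSC hypoxia). For 72 comparisons at named regions there were 805 alternative values, many of them fixed in advance. Joining under 1000 bp, no minimum breadth and counting only regions with a peak in both lists could not change a value. Nor could leaving out chromosome X or regions near centromeric bands. Of the 805, 1 had the other sign and 3 came under 2-fold, each with joining under 5000 bp: 0.23 at 7q21.11 (from 79775056), −0.62 at 19p13.12, −0.67 at 10q25.1 and −0.84 at 3q13.2. The cause was not tested.

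No paired analysis was possible because the lists do not tell libraries A and B apart, and leaving out a replicate was not possible for the same reason. Not run were alternatives that need the caller's significance, or gene positions on hg19 (start site windows, shared start sites, all annotated genes, gene lists). Depth is unknown, so a missing narrow peak cannot be told from one under the caller's threshold.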

Other observations

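Peak width was also summed over fixed windows of 100 kb, which were ranked by the difference between lists. Whether changes cluster more than by accident was not tested. A window can hold only part of a domain, as at 7q33. The window on chromosome 5 from 65200001 (5q12.3) held 9.31 kb of H3K4me3 peaks in ESF normoxia, 6.01 kb in ESF hypoxia and 38.2 kb in DSC hypoxia, the largest difference between DSC and hypoxic ESF over all windows. Next came chromosome 7 from 134500001 (7q33), with 7.59, 21.1 and 49.1 kb, which was also the largest gain of hypoxic over normoxic ESF. At 2q35 (chromosome 2 from 216200001), in the band that holds FN1, the fibronectin gene, coverage was 5.55 kb in ESF normoxia, 18.9 kb in ESF hypoxia and 12.4 kb in DSC hypoxia. At 6p22.2 (chromosome 6 from 26700001) it was 6.33, 18.8 and 12.4 kb.

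Losses in hypoxic ESF were largest at 12q23.3 (chromosome 12 from 104600001), with 30.2 kb in ESF normoxia, 10.7 kb in ESF hypoxia and 14.1 kb in DSC hypoxia, and at 4q26 (chromosome 4 from 114800001), with 22.4, 5.08 and 5.80 kb. A window at 5q15 (chromosome 5 from 95200001) was low in hypoxic ESF alone, with 21.7, 7.18 and 25.3 kb. DSC had the largest deficits against hypoxic ESF at 18p11.31 (chromosome 18 from 3200001; 23.5 kb in ESF hypoxia, 12.9 kb in DSC) and 22q12.3 (chromosome 22 from 36700001; 24.2 and 14.1 kb).

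The tests of other differences between cultures or libraries, of repeat-rich sequence, of the numbers gained and lost near centromeres and of a uniform change of width were chosen after the results were seen. Chromosome X had 1.147 times the autosome-scaled peak count in ESF hypoxia against ESF normoxia. Narrow peaks near the calling threshold are a candidate explanation: among peaks of 1000 bp or more the X ratio was 1.018, within the 0.945 to 1.044 of the autosomes, and under 1000 bp it was 1.37 (360 and 284 peaks). A change in 1 segment of X stays open, since the p arm ratio was 1.077 (interval 0.935 to 1.24) and the q arm ratio 1.21 (1.06 to 1.38), which overlap. An effect of oxygen, which was not tested, cannot be told apart from other differences between cultures or libraries, with 1 list per condition.

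Of the 10 broadest regions gained in hypoxic ESF, 6 lay within 5 Mb of centromeric or heterochromatic bands, and 11 of all 45 of 3 kb or more (24.4%) did, against 8.00% of the 6662 regions of that size. Without the 10 in which this was seen, 5 of 35 (14.3%, interval 6.26 to 29.4%) did, which does not clearly exceed 8.00%, so a part played by repeat-rich sequence stays open. Among the 79 lost regions of that size the share was 5.06% (4 regions, interval 1.99 to 12.3%), which had been set beforehand as evidence against calls in such sequence coming and going at random, but it depends on how many regions were lost elsewhere, and by number the 11 gained of 15 (73.3%, 48.0 to 89.1%) do not exclude an even balance. Over regions of any breadth, 496 near such bands were gained and 465 lost (51.6% gained, 48.5 to 54.8%), which were 9.20% of all gained and 6.72% of all lost regions. Random coming and going therefore stays open too, as do a difference in input or mapping between the lists and an effect of oxygen, which were not tested.

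H3K4me3 regions were narrower in ESF hypoxia than in ESF normoxia across the range of breadth. In each of 10 equal groups of the shared regions by breadth, more than 50% were narrower, from 52.4% (interval 50.4 to 54.4%) to 72.8%. Counted from the narrowest, the share was 52.9, 52.4 and 52.5% in groups 2, 3 and 4, and 70.6% in group 10. More than 50% in each group had been set beforehand as the sign of a lower sensitivity of the ESF hypoxia list. A narrowing of the mark itself would give the same, so these shares cannot tell the explanations apart. A lower sensitivity may still account for part of the shift. It may also account for part of the greater breadth of DSC hypoxia, which was compared with the same list. One uniform change of width is argued against, since the median log2 ratio ranged over 0.101 across the 10 groups, from −0.12 to −0.02, and the highest range in 1000 resamples of groups with equal medians was 0.0930. Without the narrowest group these values were 0.0964 and 0.0819. An effect of hypoxia on the mark stays open and untested, because oxygen and the single list per condition change together.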
